A study of Homo sapiens with 2 samples.

How the data were processed

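RNA was measured on Affymetrix Human Genome PrimeView arrays, which carry several probe sets for many genes, in A549 cells, an established line from a human non-small cell lung cancer. There were 2 arrays. One held RNA of untreated cells and the other RNA of cells given sodium butyrate, a short-chain fatty acid that inhibits histone deacetylases. Per the labels' protocols, cells were grown for 24 h in medium with 10% fetal bovine serum, butyrate was then added for 24 h, and biotin-labelled cRNA was made from 15 µg of total RNA with a 3′ in vitro transcription kit, a kind that primes at the poly-A tail. For the untreated cells the labels used here give no further culture or harvest time, so time in culture may differ between the arrays. The labels disagree on the dose. The sample title and treatment label give 5 mM and the treatment protocol gives 9 mM, so the sample is called the butyrate array throughout.

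The authors deposited RMA values on the log2 scale for 49395 probe sets per array, of which 102 were control probe sets. RMA corrects background, normalises arrays to a common distribution and summarises the probes of a set. That the values are RMA comes from the name of the deposited table, and the log2 scale was checked against the authors' ratio column. The submitters' processing notes name Affymetrix Expression Console and Partek, with no version. A deposited table of the authors' analysis of variance gives a linear ratio per probe set, per the file headers, and a second table lists the probe sets at least 2-fold apart. The sums of squares in the analysis of variance table exceeded what 2 arrays can give in 99.8% of probe sets (tolerance 0.0001). Further arrays, not analysed here, therefore entered it and may have shared the normalisation. The residual sum of squares there was 0 and no p-value was given. Another 6 columns of values in the deposited files carry names that match no sample label, and they were not used. Their names are those of the 2 sides of the authors' ratio, which matched butyrate over untreated in all 49395 probe sets. They need not be further arrays.

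Probe sets were named from the array maker's annotation of 2011, which is on GRCh37, and all coordinates given are alignments of probe sets from that annotation. Of the probe sets, 47340 carried 1 gene symbol, 1457 several and 588 none. The 10 control probe sets that carry 1 symbol were left out of these counts, while the other control probe sets are in them. Symbols were updated through the Entrez gene number with a RefSeq gene table of GRCh38, used for names only. It held 47089 of the 47340 probe sets, and the other 251 kept the symbol of the file. No probe set with several symbols was given to a gene.

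A gene was represented by its probe set with the highest mean over both arrays, and the difference was the log2 value on the butyrate array minus that on the untreated array. A gene counted as above the floor where its brighter array reached that array's median over the non-control probe sets, which was 6.05 for untreated and 6.10 for butyrate. The floor is no limit of detection, since signal from unbound or cross-hybridising probes remains in RMA values, and folds of genes that were dim on one array are compressed. Genes were counted as higher or lower at a 2-fold difference or more. With 1 array per group no test, p-value or spread between replicates was possible, and the number of arrays limits the precision. The spread between different probe sets of one gene was used as a technical measure, and it holds no biological spread.

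Gene lists were fixed before the data were examined, as were the thresholds, the alternative settings and the rule for naming genes. There were 12 primary and 29 secondary lists with 759 symbols, of which 747 matched a gene on the array. For each list the median difference over members above the floor was given with its percentile among 10000 random lists of the same size, drawn within 20 bins of mean value. A list was said to stand apart where it lay in the outer 5% of the random lists, both ends together, and 2.05 of the 41 lists would do so by chance. The percentile describes these 2 arrays and is no test of the treatment. Named genes were the 12 with the largest difference in each direction whose other probe sets above the floor, if any, had the same sign, up to 4 members of each list with the largest absolute difference, and a fixed set of cell cycle, apoptosis, histone deacetylase, adhesion and reference genes. Where 5 or fewer members of a list were past 2-fold, the others named beyond this rule were chosen after their values were seen. Some genes that the rule takes, and 1 primary list, which did not stand apart, are not reported here, though they stay in the counts and medians given.

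The alternatives were the mean or the median of a gene's probe sets, leaving out probe sets that can bind several transcripts (identifiers ending in _x_at or _s_at), no floor or a floor at the 75th percentile, centring, quantile normalisation, a loess with span 0.3, thresholds of 1.5-fold and 3-fold, and random lists not matched on value. Scaling to the 3′ probe sets of the poly-A spike-ins was added after the data were seen. The procedure was tested on simulated butyrate and untreated arrays with a noise SD of 0.2 per probe set. Among 11839 simulated genes it recovered 99 of 100 genes shifted by log2 2 and 98 of 100 shifted by log2 1.5, with 1 false call. It also placed apart 20 of 20 lists of 20 genes shifted by 0.5 and 9 of 200 unshifted lists. The simulated noise was milder than the data, where the pooled SD between probe sets of one gene was 0.349. The differences of the measured genes had an SD of 0.855. The simulation therefore checks that the steps work and gives no error rate for these arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.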

Results

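Gene expression was measured in A549 lung cancer cells without treatment and after 24 h of sodium butyrate, to ask how a high concentration of this histone deacetylase inhibitor altered the transcriptome. Each group had 1 array and no replicates, so every difference below describes these 2 arrays. Log2 RMA values ran from 2.40 to 14.8 on the untreated array and from 2.46 to 14.9 on the butyrate array, and Pearson's r between the arrays was 0.956 across all probe sets, which are not independent replicates. Of 19040 genes with a probe set of their own, 12176 were above the floor.

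Genes of cell division and DNA synthesis were lower in the butyrate array, while known targets of histone deacetylase inhibitors, histone genes and metallothioneins were higher. At a threshold of 2-fold, 1038 genes were higher and 1114 lower in the butyrate array, together 17.7% of the genes above the floor, so that 48.2% of the genes past the threshold were higher. With the butyrate array scaled to the poly-A spike-in controls instead, an alternative added after the data were seen, 599 genes were higher and 1898 lower, a share of 24.0%, and the median difference of all genes above the floor was −0.35 in place of −0.04. At 4-fold, 205 genes were higher and 263 lower, and at 8-fold 52 were higher and 65 lower. Different probe sets of one gene gave differences with a pooled SD of 0.349 on the log2 scale over 6756 genes. Of 1187 genes past 2-fold with at least 2 probe sets above the floor, all probe sets had the same sign in 1133 (95.5%) and opposed signs in 54. The authors' deposited 2-fold table lists 5405 probe sets at least 2-fold apart, with 3029 ratios above 1 and 2376 below 1. It counts probe sets, with no floor and more than 1 for many genes, so its balance cannot be set against that of the genes. The ratios in their analysis of variance table matched butyrate over untreated in all 49395 probe sets (relative tolerance 0.001).

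**Figure D1:**
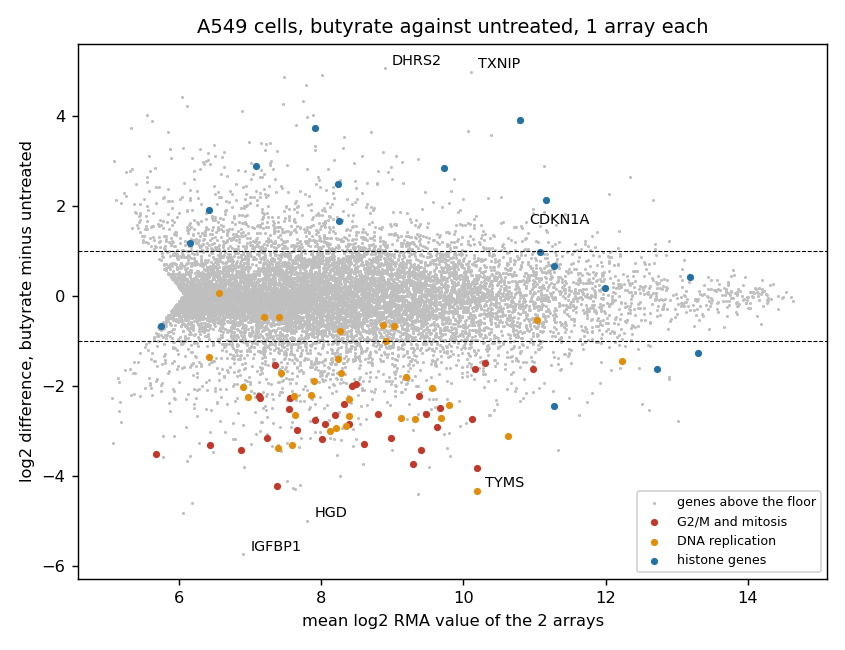
Log2 difference (butyrate minus untreated) of each gene above the floor, as grey points, against its mean log2 RMA value over the 2 arrays, with members of the G2/M and mitosis, DNA replication and histone lists in colour and dashed lines at 2-fold. The 33 measured G2/M genes all lie below the lower line, and 9 of 17 histone genes lie above the upper one.

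With each gene read by its brightest probe set, the largest higher value belonged to DHRS2, a short-chain dehydrogenase/reductase, which was 33.4-fold higher in the butyrate array (log2 6.37 against 11.4; chromosome 14, 24112253 to 24114846). TXNIP, the thioredoxin-binding arrestin, was 31.6-fold higher (chromosome 1, 145438510 to 145442592) and 5 of its 5 probe sets lay between log2 4.98 and 5.88, the first being its brightest, while its relative ARRDC4 was 25.7-fold higher. TEX19, a germ-cell gene, was 30.1-fold higher, KLLN was 29.1-fold higher, and the microRNA host transcript MIR7-3HG was 21.5-fold higher. The fatty acid hydroxylase CYP4F2 and the synaptotagmin SYT11 were higher by log2 4.33 and 4.22, the G protein subunit GNG7 by 4.12, the muscle protein gene MYOT by 4.02 and NATD1 by 3.98. The lowest probe sets above the floor gave 1.23 for CYP4F2, 1.36 for GNG7 and 2.81 for ARRDC4. ULBP2, a ligand of the natural killer cell receptor NKG2D, was higher by 4.27 in its 1 probe set above the floor, but the median over all 3 of its probe sets was −0.061.

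At the other end, IGFBP1, an insulin-like growth factor-binding protein, was 53.3-fold lower in the butyrate array (log2 9.77 against 4.03; chromosome 7, 45927955 to 45933261). HGD, the homogentisate dioxygenase of tyrosine breakdown, was 31.6-fold lower. SPC25 and ZWINT, both of the kinetochore, had log2 differences of −4.81 and −4.39, HJURP, the chaperone of the centromeric histone, −4.25, and CDCA5, which holds sister chromatids together, −4.10 in its brighter and −1.17 in its other probe set. TYMS, the thymidylate synthase, was at −4.32 (log2 12.4 against 8.04; chromosome 18, 657618 to 673764), and the S and G2 phase cyclin CCNA2 was 18.7-fold lower. SERPINB11, KCTD15, ANXA13 and TM4SF20 had differences of −4.60, −4.27, −4.19 and −3.99, and the smallest of KCTD15's 3 probe sets above the floor was −1.61.

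Genes that histone deacetylase inhibitors are known to induce were higher as a group, with a median of 1.26 on the log2 scale. Of the 15 members, 8 were at least 2-fold higher, 0 lower and 7 within 2-fold, and the median exceeded that of all random lists (percentile 100). Besides DHRS2 and TXNIP, the metallothionein MT1X was higher by 3.59. CDKN1A, which encodes the CDK inhibitor p21, was 2.87-fold higher (log2 10.1 against 11.6), and its 2 probe sets gave 1.39 and 1.52. The CDK inhibitors as a list did not stand apart (median 0.18, percentile 78.3), with CDKN2D higher by 1.21, CDKN2C at −1.14 and CDKN1B, which encodes p27, at −0.60. Over the median of each gene's probe sets their median was 0.88, at percentile 98.7.

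Every list of the proliferation machinery was lower in the butyrate array. All 33 measured G2/M and mitosis genes were at least 2-fold lower, with a median of −2.72, and CCNA2, UBE2C, which tags mitotic cyclins for destruction, AURKA and NDC80 had differences of −4.22, −3.81, −3.71 and −3.51. CDK1 was at −3.40, CCNB1 at −2.72, the proliferation antigen MKI67 at −2.74 and TOP2A at −1.60. In the DNA replication list 26 of 34 genes were at least 2-fold lower and 0 higher, with a median of −2.11. TYMS was lowest, followed by the origin recognition subunit ORC6 at −3.38, MCM10 at −3.30 and the helicase subunit MCM7 at −3.10, while PCNA was at −1.43. G1 and G1/S regulators were lower in 7 of 14 and higher in 0, with a median of −1.10. CDC25A was at −2.90, the p27 ligase subunit SKP2 at −2.38, CCND1 at −1.69, E2F2 at −1.59 and E2F1 at −1.32, against −0.12 for CCNE1 and −0.16 for MYC. The DNA repair list was lower in 12 of 22 genes with a median of −1.13, led by RAD51AP1 at −3.56, FANCI at −3.15, BRCA1 at −2.78 with probe sets up to −1.04, and BLM at −2.44. All these lists lay below every random list (percentile 0).

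Apoptosis genes went both ways and did not stand apart as lists. Of 19 pro-apoptotic genes above the floor, 4 were at least 2-fold higher and 1 lower (median −0.12 and mean 0.03, which differ in sign, percentile 30.1). The death receptor gene TNFRSF10B was higher by 1.43, and BBC3, BAK1 and BIK, of the BCL-2 family, by 1.30, 1.16 and 1.06, while BID was at −1.44. The lowest probe sets above the floor gave only 0.29 for BBC3 and 0.24 for BAK1. Of 9 anti-apoptotic genes 1 was higher and 2 lower (median −0.44, percentile 6.53). BIRC3, an inhibitor of apoptosis, was higher by 2.33, whereas CFLAR, which blocks caspase-8, and BIRC5, also a mitotic gene, were at −1.21 and −2.62. BCL2 was at −0.21, BAX at 0.14 with probe sets from −0.38 to 0.14, and BCL2L1 at −0.61 with 3 probe sets from −0.61 to 0.99, so that neither gene has a settled sign.

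Histone genes were higher as a group, with a median of 1.17 over 17 members above the floor (percentile 100). Without a floor, over all 30 measured histone genes, the median was 0.38, and it was 0.62 with the median of each gene's probe sets. The linker histone H1-2 was higher by 3.91 (chromosome 6, 26055484 to 26056698), H2AC11 by 3.74, H3C10 by 2.89 and H2BC5 by 2.84, and 9 members were at least 2-fold higher in all. The 3 lower ones were H2AX at −2.44, H2AZ1 at −1.61 and H4C3 at −1.26. Histone genes are near-identical in sequence, so a value cannot always be given to 1 gene. H1-2 and H3C10 were each read above the floor by only 1 probe set, of the _x_at or _s_at kind that can bind several transcripts. The histone deacetylase and sirtuin genes were near the edge of the random lists (median 0.31, percentile 97.0, 2 of 18 higher and 0 lower). SIRT4 was higher by 2.45 and HDAC5 by 1.40, while HDAC3, HDAC1 and HDAC2 were at 0.97, 0.27 and −0.13. Chromatin writers and bromodomain proteins were lower (median −0.37, percentile 2.20). Of 22 genes 3 were lower, namely UHRF1 at −2.47 and SUV39H1 at −2.30, which maintain DNA methylation and heterochromatin, and EZH2 at −1.20, whose median over all probe sets was 0.27. Other probe sets of UHRF1 and SUV39H1 reached only −0.16 and −0.30. The demethylase gene KDM5B was higher by 1.27. This list did not stand apart with the median of probe sets, without _x_at and _s_at probe sets or under another floor.

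**Figure D2:**
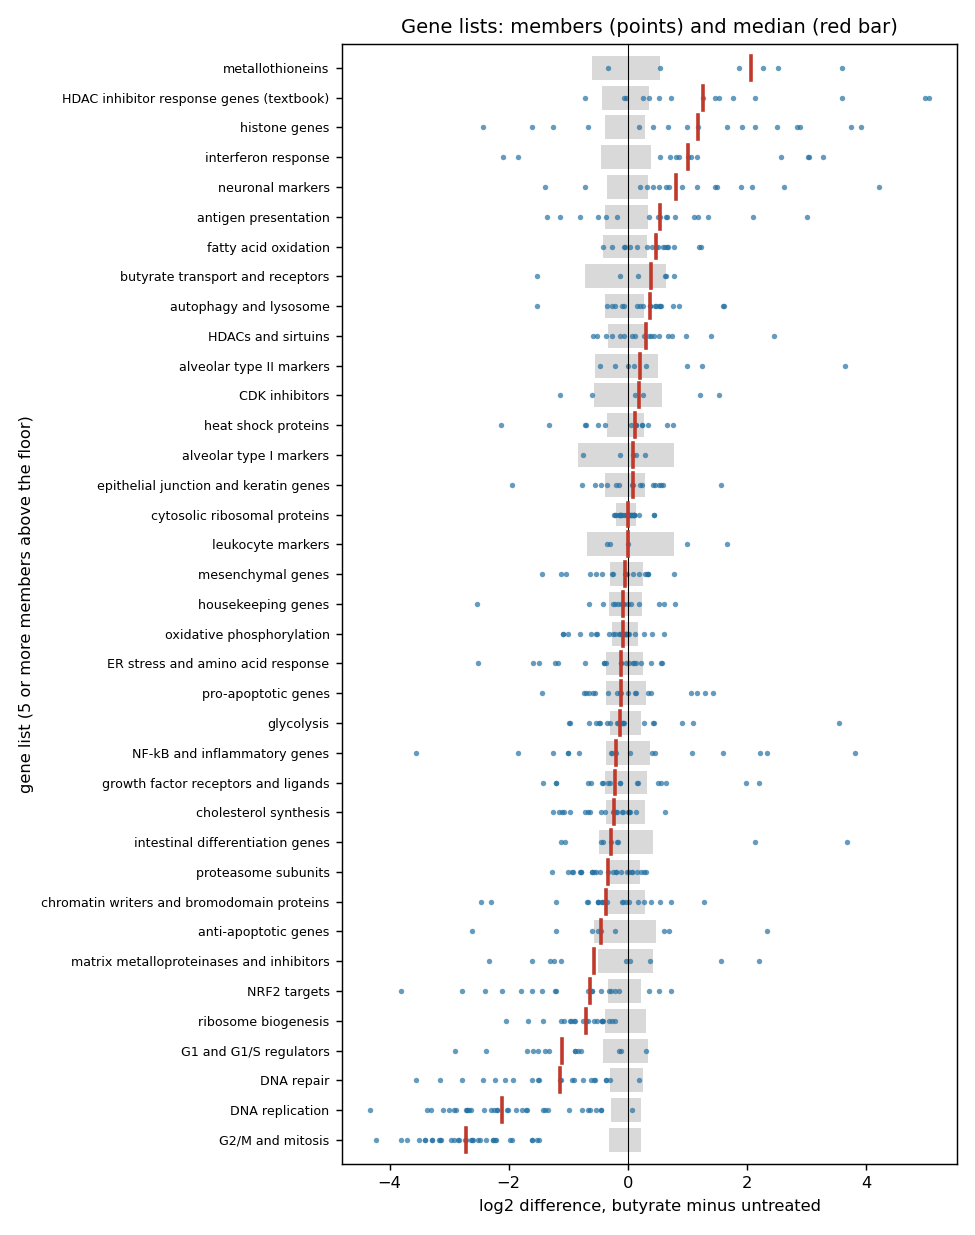
Log2 difference (butyrate minus untreated) of the members above the floor (points) and their median (red bar) for each reported gene list with at least 5 such members, with the range that held 95% of the medians of 10000 matched random lists in grey. The G2/M and mitosis median of −2.72 and the metallothionein median of 2.07 are the lowest and the highest.

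Epithelial and mesenchymal genes did not separate the arrays as lists. Epithelial junction and keratin genes had a median of 0.08 (percentile 79.8), with 1 of 17 higher and 1 lower. These were the keratins KRT19, higher by 1.57, and KRT7, at −1.94, and the cadherin gene CDH1 was at 0.23. Mesenchymal genes had a median of −0.05 (percentile 46.0) with 3 of 17 lower. Among these, the receptor kinase gene AXL was at −1.43 and −0.46 in its 2 probe sets, and VIM, which encodes vimentin, at −1.05 in both of its own. With a floor at the 75th percentile the mesenchymal median was −0.59, at percentile 1.36. Matrix metalloproteinases and inhibitors were lower (median −0.58, percentile 1.32), with 5 of 10 lower and 2 higher. Among the lower ones, the urokinase gene PLAU was at −2.32, MMP24 at −1.60, MMP7 at −1.31 and PLAUR, the urokinase receptor gene, at −1.24. TIMP2, an inhibitor of these proteases, and MMP9 were higher by 2.20 and 1.57. This list no longer stood apart with the mean or median of probe sets, without _x_at and _s_at probe sets or without a floor.

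Metallothioneins and NRF2 targets moved apart from each other as lists. Metallothioneins were higher in 4 of 6 genes, with a median of 2.07 (percentile 100), from MT3 at 1.87 and MT2A at 2.27 to MT1F at 2.52 and MT1X at 3.59. The 2 probe sets of MT2A gave 0.32 and 2.27, and without _x_at and _s_at probe sets the median of the list was 0.98. The NRF2 targets, which are strongly expressed in untreated A549 cells, were lower (median −0.64, percentile 0.03), with 9 of 20 lower and 0 higher. Not all members fell, since SRXN1, GCLC and TXNRD1 were higher by 0.73, 0.52 and 0.36, each under 2-fold, and HMOX1 was at −0.21. ABCC3, a drug efflux pump, was at −3.80 and −1.54 in its 2 probe sets, the aldo-keto reductase AKR1B10 at −2.78 from log2 14.4, ABCC2 at −2.40 and ALDH3A1 at −2.11. Fatty acid oxidation genes were higher (median 0.47, percentile 99.7). Only ETFDH, at 1.22, and HADHB, at 1.20, of its 17 genes were past 2-fold. Autophagy and lysosome genes were also higher (median 0.37, percentile 99.4), with ATG12 higher by 1.61, MAP1LC3B by 1.59 and GLA at −1.53 among 20. Spike-in scaling brought the medians of these 2 lists to 0.16 and 0.060.

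Several metabolic and stress lists did not stand apart. Cholesterol synthesis had a median of −0.24 (percentile 11.3) with 4 of 22 lower, which were FDPS at −1.25, ACAT2 at −1.16, EBP at −1.10 and NSDHL at −1.08. The cholesterol synthesis list stood apart only with the median of each gene's probe sets (median −0.37, percentile 2.24), and its median was −0.55 with spike-in scaling, at percentile 10.6. Glycolysis had a median of −0.13 and a mean of 0.06, which differ in sign (percentile 22.8), and the 2 genes past 2-fold, the aldolase ALDOC and the kinase PDK1, were higher by 3.55 and 1.10, where the 5 probe sets of ALDOC ranged from 0.38 to 3.55. The list of endoplasmic reticulum stress and amino acid response genes had a median of −0.12 (percentile 31.6), with 5 of 20 lower, among them XBP1 at −2.51, TRIB3 at −1.60, PSAT1 at −1.49, SLC7A11 at −1.22 and ATF4 at −1.17. Heat shock protein genes had a median of 0.12 and a mean of −0.20, again opposed in sign (percentile 85.4), with HSPH1 at −2.14 and HSPE1 at −1.32. Oxidative phosphorylation genes were at a median of −0.09 (percentile 30.9), where 3 of 26 genes were at least 2-fold lower, CYC1 and NDUFA9 both at −1.09 and NDUFS3 just past the threshold. Butyrate transporters and receptors were at 0.40 (percentile 90.3), and the efflux pump ABCG2 was the only 1 past 2-fold of 6, at −1.53.

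Interferon response genes were higher, with a median of 1.01 over 13 genes (percentile 99.99), of which 7 were at least 2-fold higher. BST2, the tetherin gene, was higher by 3.27, ISG15 by 3.05, IFIT1 by 3.02 and IFI6 by 2.57. The antiviral synthetase genes OAS3 and OAS1 ran the other way, at −2.09 and −1.84. Without a floor, over all 22 listed genes, the median was 0.35. Antigen presentation genes were higher with a median of 0.53 (percentile 99.8), with 5 of 17 higher and 2 lower. The class I gene HLA-F read log2 5.79 and 8.79, HLA-B and HLA-E were higher by 2.09 and 1.35 and the class II gene HLA-DMA by 1.18. TAPBP, the peptide-loading factor, was at −1.36 with probe sets up to −0.16, and the immunoproteasome subunit PSMB8 was at −1.14. Without probe sets that can bind several transcripts this median was −0.36, and HLA-C and HLA-E then had no probe set left and HLA-B was read only by a dim probe set, at −0.021. Of the 10 probe sets of HLA-F, 4 were above the floor and all of these were higher, by at least 1.18, while the median over all 10 was −0.054. NF-kB and inflammatory genes did not stand apart (median −0.20 and mean 0.10, opposed in sign, percentile 16.03). The chemokine CCL20 was higher by 3.81, and BIRC3, IL1A, TNFAIP3 and CXCL8 by 2.33, 2.22, 1.59 and 1.07, against −3.56 for CXCL5, −1.85 for NFKB1 and −1.26 for CXCL1.

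Genes of other cell types were examined in the same way. Neuronal markers were higher in the butyrate array (median 0.81, percentile 99.99), with 7 of 16 at least 2-fold higher, among them SYT11, SYT1 at 2.61, the chromogranin CHGA at 2.08 and MAPT, which encodes tau, at 1.91 with probe sets from 0.23 to 2.01. Spike-in scaling brought the median of this list to 0.49. The presynaptic gene SNAP25, at −1.39, was the only 1 lower. Alveolar type II markers were at 0.21 (percentile 84.8), where LAMP3 and CTSH were higher by 3.64 and 1.24 and no surfactant gene above the floor was past 2-fold. With a floor at the 75th percentile the alveolar type II median was 0.996 (percentile 98.0), and with spike-in scaling it was −0.10. Alveolar type I markers had a median of 0.09 and a mean of −0.07 (percentile 64.6, 0 of 5 past 2-fold). Intestinal differentiation genes, which butyrate is known to affect in colon cells, had a median of −0.28 and a mean of 0.24 (percentile 11.96). KRT20 and the peptidase ANPEP were higher by 3.67 and 2.13, and CEACAM5 and LGALS4 were at −1.12 and −1.06. With the median of each gene's probe sets the median of the intestinal differentiation genes was −0.67 (percentile 2.20). Few germ line, fibroblast, endothelial and leukocyte markers were above the floor. Their medians were 1.12 over 2 genes (percentile 93.5), −0.22 over 2 (37.1), 0.20 over 3 (70.7) and 0.00 over 5 (55.8). MAGEC2, a cancer testis antigen, was higher by 1.56 and the monocyte marker CD14 by 1.66. Growth factor receptors and ligands were at −0.22 (percentile 14.0), with HBEGF and AREG, both ligands of the epidermal growth factor receptor, higher by 2.21 and 1.98, and VEGFC, NRG1 and EREG at −1.43, −1.21 and −1.20.

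Cytosolic ribosomal protein genes had a median of 0.00455 with 0 of 32 past 2-fold (percentile 64.2), but nearly all read close to the top of the scale, where a shift is compressed. Ribosome biogenesis genes were lower (median −0.69, percentile 0.01), with 5 of 21 lower, namely UTP20 at −2.05, DKC1, which encodes dyskerin, at −1.68, NOP16 at −1.42, RRS1 at −1.12 and NOP56 at −1.07. Proteasome subunits were lower (median −0.33, percentile 1.56), with PSMB5 at −1.28 and PSMC3 at −1.01 the 2 of 25 past 2-fold, and did not stand apart with the mean or median of probe sets, without _x_at and _s_at probe sets or after quantile normalisation. Reference genes had a median of −0.09 (percentile 34.5). GAPDH was at −0.09 and ACTB at −0.41, and the tubulin gene TUBA1B, at −2.53, was the only 1 of 15 past 2-fold. In all, 8 lists were higher, 9 lower and 24 did not stand apart.

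The control probe sets differed between the arrays as follows. Poly-A spike-ins, bacterial transcripts added to the RNA before labelling, were higher on the butyrate array in 24 of 24 probe sets, with a median of 0.31 at the 3′ end, 0.36 in the middle and 0.60 at the 5′ end. Hybridisation spike-ins, added after labelling, had a median of 0.02 over 18 probe sets and background probe sets −0.04 over 23. The 3′ minus 5′ value was 0.20 on the untreated and 0.14 on the butyrate array for GAPDH, and 1.97 and 1.81 for ACTB. For the dap, thr, phe and lys spike-ins it was 2.07, 3.17, 0.95 and −0.21 on the untreated array, and 1.12, 2.65, 0.87 and −0.013 on the butyrate array, so that it fell in dap and thr, changed little in phe and rose in lys.

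**Figure D3:**
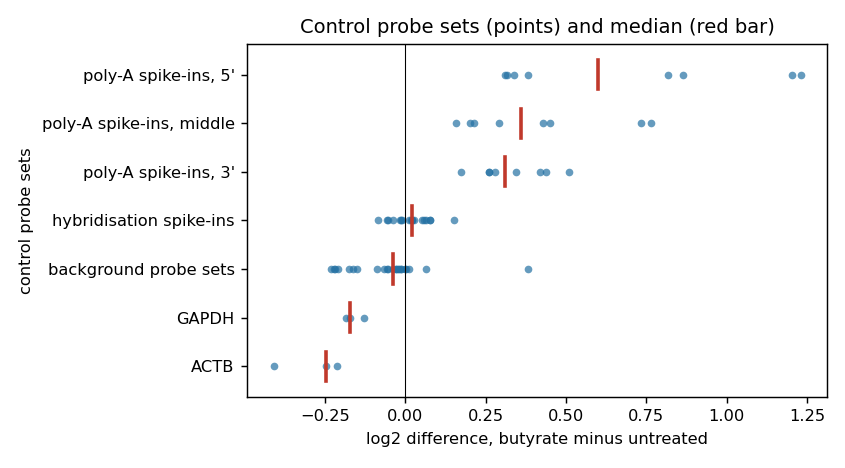
Log2 difference (butyrate minus untreated) of single control probe sets (points) and the median of each kind (red bar). All 24 poly-A spike-in probe sets lie above 0, while the hybridisation spike-ins centre on 0.02.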

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

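All tests in this part were chosen after the results were seen, except that of histone probe sets without those that can bind several transcripts. The poly-A spike-ins were higher on the butyrate array in 24 of 24 probe sets. A brighter hybridisation or scan that was left after normalisation is argued against as the cause by the hybridisation spike-ins, whose median shift was 0.02 (0.01995, SD 0.0582). Longer labelled products alone would leave the 3′ ends in place, yet the lowest 3′ shift was 0.18 (0.1751), above the highest hybridisation spike-in at 0.15. Less messenger RNA per total RNA in the butyrate sample and more spike-in added to it cannot be told apart: the 18S rRNA probe sets, with a median shift of 0.11, read between log2 13.5 and 14.3, near the top of the scale, and of the 28S rRNA probe sets (−0.09, 0.37 and 0.49) the one with the highest shift, at 11.3 and 11.8, goes with less messenger RNA but is a single probe set.

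Histone genes were higher in the butyrate array although genes of DNA replication were lower. Without probe sets that can bind several transcripts, the median over the 10 remaining histone genes was 0.87 (percentile 99.97), which argues against cross-hybridisation as the whole cause. More cells in S phase is argued against by the DNA replication median of −2.11. Polyadenylated histone transcripts, which a poly-A primed label reads, may be more abundant after butyrate, as a hypothesis that these 2 arrays did not test. Among histone genes, the variants H2AX and H2AZ1 were lower, at −2.44 and −1.61.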

How the results depend on the processing

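Scaling to the poly-A spike-ins was chosen after the data were seen and the other settings before. No paired analysis was possible because each group had 1 array. The series value table was used throughout, and the planned exchange with the annotated expression table was not run, since its value columns match no sample label. Depth on an array is signal over background, and genes near the floor have compressed differences. Where no reason is given, the cause was not tested.

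The G2/M, DNA replication, G1, histone and histone deacetylase inhibitor response lists stood apart in the same direction under every setting, with medians from −3.03 to −2.51, −2.42 to −2.03, −1.42 to −0.89, 0.38 to 1.33 and 0.95 to 1.46. Centring and spike-in scaling move a list and its random lists alike, so these settings could hardly change whether a list stood apart. The share of higher genes, 48.2%, was 51.4% with the mean and 52.5% with the median of probe sets, 51.6% without _x_at and _s_at probe sets, 50.4% without a floor, 43.7% with the floor at the 75th percentile, 45.7% with centred arrays and 44.8% at 3-fold. By construction the counts moved with the threshold, to 2186 higher and 2279 lower at 1.5-fold and to 374 and 460 at 3-fold. Spike-in scaling lowered all genes of the butyrate array alike, giving 599 higher, 1898 lower and a share of 24.0%. The CDK inhibitors came to stand apart with the median of probe sets (0.88), and the mesenchymal genes with the 75th percentile floor (−0.59). The histone deacetylase and sirtuin genes, close to the edge of the random lists, passed it without _x_at and _s_at probe sets (0.43), without a floor (0.31) and with quantile normalisation (0.34). They also passed it with spike-in scaling (−0.00098), which moves the list and the random lists alike and therefore adds no evidence.

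Reversals were counted for genes at least 2-fold apart, so that BAX and BCL2L1, whose probe sets oppose each other, are not among them. With the median of probe sets, dim ones included, the sign reversed for EZH2 (0.27), HLA-F (−0.054) and ULBP2 (−0.061). Without _x_at and _s_at probe sets it reversed for HLA-B (−0.021) and ULBP2 (−0.047), which then had only dim probe sets, and for the antigen presentation list (−0.36), which then lacked HLA-C and HLA-E, among others. Of the secondary lists, the proteasome, matrix metalloproteinase and chromatin writer lists lost their place in 12 list and setting pairs, and the cholesterol, intestinal and alveolar type II lists gained one in 3. Of the named genes, 1537 gene and setting pairs moved by less than the spread between probe sets and 119 by more without a reversal.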

Other observations

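Gene families sharing a symbol stem were screened after the results were seen, and the shift of the background probe sets and the other probe sets of the crossing genes were also examined after that, while the count of dim genes was planned. Of 384 families with at least 5 members above the floor, 20 lay at the upper and 30 at the lower end of matched random lists, where chance gives 9.6 at each. The subunits of the vacuolar proton pump that acidifies lysosomes were higher, with a median of 0.84 over 18 genes, 8 of them at least 2-fold higher and 0 lower. ATP6V1D was higher by 1.73, ATP6V0A1 by 1.69 and ATP6V1C2 by 1.48. The Bardet-Biedl syndrome genes had a median of 1.04 over 7, of which 4 were at least 2-fold higher and 0 lower, with BBS10 and BBS12 higher by 1.87 and 1.75. The intraflagellar transport genes had a median of 0.67 over 17, with a pseudogene among them, but only 2 were at least 2-fold higher and IFT172 and IFT74 were at −0.68 and −0.46. Of the other families with cilium or centrosome genes, CFAP (median 0.37) and CEP (−0.13) did not lie at either end. The axonemal dynein assembly factors had a median of 0.61 over 7, led by DNAAF3 at 2.66 and DNAAF4 at 1.51.

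Among the lower families, the HOXB cluster had a median of −1.39 over 7 genes, with HOXB3, HOXB5, HOXB6, HOXB7 and HOXB8 between −1.72 and −1.34, and the more distant HOXB13 at 0.16. The augmin subunits, which branch spindle microtubules, had a median of −1.18 over 8, with HAUS7 at −1.87 and HAUS2 at −1.72. Splicing factors of the SR family were at −0.89 over 11, with 5 at least 2-fold lower, among them SRSF7 at −1.73 and SRSF2 at −1.66. Nucleoporins were at −0.68 over 22 and mitochondrial ribosomal proteins of the small subunit at −0.63 over 28. These families had the same sign without _x_at and _s_at probe sets, with the median of probe sets and under every scaling tried, spike-in scaling included, but their sizes varied. With spike-in scaling the medians of the higher families fell to 0.52 for the proton pump, 0.73 for the Bardet-Biedl genes, 0.35 for intraflagellar transport and 0.30 for the dynein assembly factors, and that of the last was 0.37 without _x_at and _s_at probe sets. The medians of these lower families were further from 0 with that scaling. Most families at either end are not described here, and some were less stable. The SMC family was at −0.81, but at 0.09 with the median of probe sets. The TUBB family was at −1.04, but at 0.43 in the 1 member left without _x_at and _s_at probe sets. Mitochondrial ribosomal proteins of the large subunit also lay at the lower end, at −0.50 over 48 genes, with 11 at least 2-fold lower.

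Whether dim genes rose past the median more often than genes above the median became dim was examined by counting. The genes counted went from below the 25th percentile of one array to above the median of the other. There were 31 such genes higher in the butyrate array, among them MIR7-3HG, MYOT, SYT11 and LAMP3, and 23 lower, among them IGFBP1, SERPINB11 and SPC25. The lower ones also held NDC80 of the G2/M list, RAD51AP1 of the DNA repair list and the kinesin genes KIF14, KIF15 and KIF20B. They therefore overlap with the fall of proliferation genes given above. Some genes of both kinds only just passed the median, such as NAT2 at log2 6.18 on the butyrate array and NOX1 at 6.05 on the untreated array. The counts of 31 and 23 do not show that more genes rose in this way than fell. Of these genes, 10 had other probe sets above the floor, and all 13 of those moved the same way as the gene, by at least 1.36 (1.35803). That size is partly set by the choice of probe sets. Each had a lower mean than the gene's own probe set, yet had to reach the floor on 1 array. Other probe sets that stayed under the floor were not counted. The shared sign, which the choice does not set, argues against noise of dim probe sets for these 10 genes. Noise may still explain single ones of the rest, and a change of both kinds of gene with treatment or between the cultures stays open. A higher background on the butyrate array cannot be judged from these values, since RMA had already corrected background and brought the arrays to a common distribution. The background probe sets, with a median shift of −0.04 (−0.03797), show only that no general rise was left after that step.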
